A study of Mus musculus with 2 samples.

How the data were processed

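Total RNA from mouse diaphragm muscle at embryonic day 18.5 was profiled on 1 Affymetrix array for each RP58 genotype, wild type and knockout. How many embryos each sample came from is not given in the sources used here. RP58 is the zinc finger transcriptional repressor now named Zbtb18. Per the labels' protocols, RNA was extracted with ISOGEN, a phenol-based reagent, and biotin-labelled cRNA was prepared from it. The extraction protocol speaks of a culture, whereas the design text describes muscle dissected under a microscope, and the tissue label is followed here. Per the series' design text in GEO, the arrays were of the mouse 430A 2.0 type, whereas the deposited probe sets matched the annotation of the larger design of the same array family, which covers more of the genome. Signals were computed by the authors with RMA (background correction, quantile normalisation and summary of each probe set's probes), per the same text, and Affymetrix Expression Console 1.1 is named in the submitters' processing notes. The deposited values are therefore log2 signals per probe set, already normalised between arrays. Which arrays were normalised together was not given in the sources used here. The sorted values of the 2 columns differed by at most 0.119, so quantile normalisation had made the distributions nearly equal, and any difference in total mRNA between the samples was removed before deposit. RMA gives no detection call, and it compresses differences of dim and of very bright probe sets.

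The deposited table held 45101 probe sets for each of the 2 samples. Of these, 34945 carried 1 gene symbol in the platform annotation, 932 carried several, 9160 carried none here and 64 were control probe sets. The annotation's Entrez identifiers were looked up in a RefSeq gene table of assembly GRCm38.p6, where 34754 of 35890 annotated probe sets had an entry, and no symbol changed. Older symbols in gene lists were resolved through that table, which in some lists led to another gene. Pigq was read in place of Gpi1 (glycolysis), Nckap1 in place of H19 (insulin-like growth factors) and Trh in place of Trf (liver). No coordinates were used except the order of genes along a chromosome.

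The measure throughout is the difference of deposited log2 signals, array labelled knockout minus array labelled wild type. With 1 array per group there is no estimate of the spread between embryos, so no test was run, no p-value is given, and no difference has a replicate check. A size rule fixed before the data were examined took its place: a gene was counted as higher or lower when its difference reached 1.5-fold (0.58 on the log2 scale). Probe sets whose mean over the 2 arrays lay under the 40th percentile of all probe sets (log2 5.52) were left out, as were those with no or several gene symbols, and each gene was read from its brightest probe set by that mean. This left 14093 genes. The only repeat measurement was that of different probe sets for a gene. Over 5675 genes with more than 1 probe set above the floor, the pooled SD of the difference within a gene was 0.28, and the median absolute disagreement of a pair of probe sets was 0.23. This covers the error of the probe sets, and also isoforms, but not embryos, dissection or hybridisation.

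In all, 43 gene lists (muscle programmes, pathways, and markers of other cell types that the dissection could hold) were fixed before the data were examined. For each, the median difference of its members above the floor was placed among 10000 random lists of the same size, matched gene by gene on mean signal in 20 bins. A list is described as standing apart when it fell outside the central 95% of these. That describes these 2 arrays and is not a test across embryos. Chance would place about 2.15 of 43 independent lists there, and several lists share members. A 95% interval of each median was taken from 2000 bootstrap draws of its genes. The genes named in the text were chosen by a rule fixed at the same time: the targeted gene, the 10 highest and the 10 lowest genes whose probe sets above the floor all went 1 way, all members of the Id family and of the myogenic regulators, and up to 3 members of each other list. Further members that are named for contrast were chosen after their values were seen.

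The functions were tested on simulated data made from the wild-type column with the probe set SD as noise and 200 changed genes among 14105 genes. The size rule recovered 93.5% of genes lowered by 1 on the log2 scale and all genes changed by 2, and it counted 3.77% of unchanged genes. Of 200 random lists of unchanged genes, 6.5% fell outside the central 95%. The alternatives were the mean over a gene's probe sets, no floor or a floor at the 60th percentile, centring by the median or by loess on mean signal (fraction 0.3), leaving out probe sets of the _s_at, _x_at and _a_at kinds, a 2-fold rule, a rule at the 95th percentile of probe set disagreement, and random lists not matched on signal. Scaling to spike-in controls and lists without shared members were added after the data were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.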

Results

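The data set comprised 2 arrays of diaphragm muscle from late mouse embryos of the C57/BL6 strain, 1 labelled wild type and 1 labelled RP58 knockout. The comparison asks how the muscle transcriptome differs when the repressor RP58 (Zbtb18) is missing. Deposited log2 signals had a median of 6.02 on the array labelled wild type and 6.03 on the array labelled knockout, and the arrays correlated with r = 0.985 over 45101 probe sets. Neither genotype was replicated, so the number of arrays limits the precision of each value that follows. A difference below about 0.28 on the log2 scale lies within 1 pooled SD of single probe sets around the mean of their gene.

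The targeted gene did not check the labels. Zbtb18 was read by 1 named probe set, whose log2 signal was 8.91 on the array labelled wild type and 9.21 on the array labelled knockout, a difference of 0.30 (1.23-fold higher). Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, and a probe set outside that part would check nothing. Groups are therefore named by their labels throughout, and each direction given here rests on those labels. The 2 samples also differed in the expression of sex-linked genes. Xist, the RNA that silences an X chromosome in females, had a log2 signal of 11.47 on the array labelled wild type and 6.96 on the array labelled knockout. The Y-linked genes Eif2s3y and Kdm5d were higher on the array labelled knockout by 4.99 and 3.31, although their signals of 3.59 and 4.09 on the array labelled wild type lay under the floor, so the sizes are uncertain. The X-linked partners Eif2s3x and Kdm6a were each lower by 0.92. The list of 6 sex-linked genes, which mixes X- and Y-linked members, had a median of -0.27. Other probe sets of Xist fell under the floor on the array labelled knockout, to 4.79 and 4.84. The Y-linked gene Uty was at 0.37 on its brightest probe set and at 3.02 on another. Together these signals read as female for the sample labelled wild type and as male for that labelled knockout. Genotype label and the sex-linked signal cannot be separated with 1 array each.

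Among the control probe sets, 18 hybridisation spike-ins had a median difference of -0.04. All 24 poly-A spike-in probe sets were lower on the array labelled knockout, with a median of -0.75 and a range of -1.17 to -0.46. When and in what ratio these control RNAs were added is not given in the sources used here. Scaling the arrays to them would raise every difference by 0.75, and all differences are therefore relative to the median gene, which differed by -0.003. For RNA integrity, the difference at the 3' probe set minus that at the 5' probe set was -0.06 for Gapdh, 0.22 for Actb, 0.65 for pyruvate carboxylase, -0.07 for the transferrin receptor, whose signals lay under the floor, and -0.83 for 18S ribosomal RNA. The values for pyruvate carboxylase and 18S RNA exceed the SD between probe sets of a gene and differ in sign.

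Genes of muscle fibres were among the lowest on the array labelled knockout, and genes mainly expressed in lung or liver were among the highest. Of 14093 genes above the floor, 918 (6.51%) were lower on the array labelled knockout by at least 1.5-fold and 540 (3.83%) were higher. At 2-fold the counts were 326 lower and 128 higher. Apart from Xist, the 10 lowest genes were Ddit4l (15.8-fold lower), Pvalb (12.9-fold), Cym (11.5-fold), Mybpc2 (10.3-fold), Art3 (6.89-fold), Rpl3l (6.8-fold), Asb5 (6.76-fold), Asb12 (6.7-fold) and Tmem182 (6.49-fold). Pvalb encodes the calcium buffer parvalbumin of fast fibres, Mybpc2 the fast myosin-binding protein C, and Rpl3l a ribosomal protein made in striated muscle. Besides Eif2s3y and Kdm5d the 10 highest genes were the lung surfactant gene Sftpc (12.5-fold higher), the interferon-inducible gene Ifi202b (6.66-fold, from a signal of 4.88 under the floor), the chemokine gene Cxcl15 (5.5-fold), the defensin gene Defb1 (4.36-fold), Spink1 (3.49-fold), and the genes Bhmt (3.84-fold), Hamp (3.82-fold) and Uox (3.34-fold), which are mainly expressed in liver. Of 538 genes past the size rule with more than 1 probe set above the floor, 400 had all probe sets on the same side of 0.

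**Figure D1:**
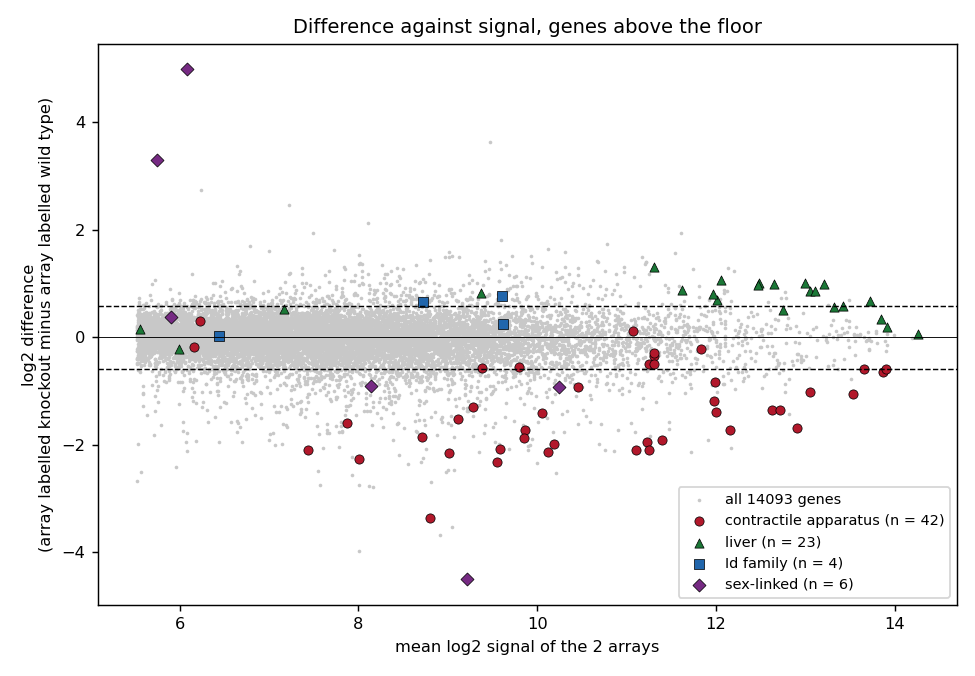
Each point is a gene above the floor, with the mean log2 signal of the 2 arrays on the x axis and the log2 difference (array labelled knockout minus array labelled wild type) on the y axis; dashed lines mark the 1.5-fold size rule. Contractile genes lie below 0 with 2 exceptions, liver genes lie mostly above 0, and the sex-linked genes hold the extremes.

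Genes of the contractile apparatus were lower on the array labelled knockout. Of 42 above the floor, 40 were below 0, 32 were lower by the size rule and 0 were higher. The list median was -1.38 (2.6-fold lower; 95% interval over genes -1.72 to -0.97) and lay below all 10000 matched random lists. Mybpc2 led the list with a difference of -3.36, and the thin filament genes Tmod4 and Lmod2 followed at -2.32 and -2.26. The differences were unequal within the list: the slow troponin T gene Tnnt1, with a wild-type log2 signal of 11.94, differed by -0.21, and skeletal actin Acta1 by -0.60 at a signal of 13.95, near the top of the scale. The only members above 0 were Mylk2 and Tpm3, and the 5 probe sets of Tpm3 ran from -1.25 to 0.55. On the same arrays, the median of liver genes was 0.82 and that of mesothelium genes 0.49, so markers of neighbouring tissues differed in the other direction from this and the other lower muscle lists.

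The medians of all 3 isoform groups were below 0. Genes of adult fast fibres had a median of -1.71, with 12 of 14 lower by the size rule, among them Pvalb (-3.69) and the calcium store protein gene Casq1 (-2.34). Genes of slow fibres had a median of -0.58, with 5 of 11 lower, namely Myl3 (-1.87), myoglobin (Mb, -1.77), Casq2 (-1.62), Myl2 (-0.82) and Myoz2 (-0.63). Embryonic and neonatal isoforms had a median of -0.55, with 2 of 7 lower. These were neonatal myosin Myh8 (-1.94) and cardiac actin Actc1 (-1.02), the actin of developing muscle, while Myh7 differed by -0.58. The 3 medians lay below 10000, 9989 and 9955 of the matched random lists, respectively, and the difference between the isoform groups was not tested.

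Genes of calcium release were lower together. Of 23 excitation-contraction coupling genes, 17 were lower and 0 higher by the size rule, with a median of -1.33 that lay below all matched random lists. Besides Pvalb and Casq1, Jph1, which encodes junctophilin of the triad, was lower by 5.65-fold at its brightest probe set (-2.50), and the mean over its 2 probe sets was -1.30. The dystrophin complex and costamere list had a median of -0.35, below 9991 of the random lists, with 7 of 18 genes lower and 1, talin (Tln1, 0.65), higher. The interval over genes of this list, -0.82 to 0.005, includes 0, and the 2 probe sets of Tln1 ran from -0.35 to 0.65. Caveolin 3 (Cav3, -2.14), dystrobrevin (Dtna, -2.06) and Pdlim3 (-1.50) led the list. Genes of the neuromuscular junction did not stand apart, with a median of -0.02. The acetylcholine receptor subunits Chrna1 and Chrnb1 each differed by -0.86, and the other 11 of 13 genes, including Erbb3 (0.58), were within the size rule. Genes of myoblast fusion and adhesion had a median of -0.01, with Cav3 lower, the receptor gene Cdon higher at 0.61 and Dysf at -0.56.

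**Figure D2:**
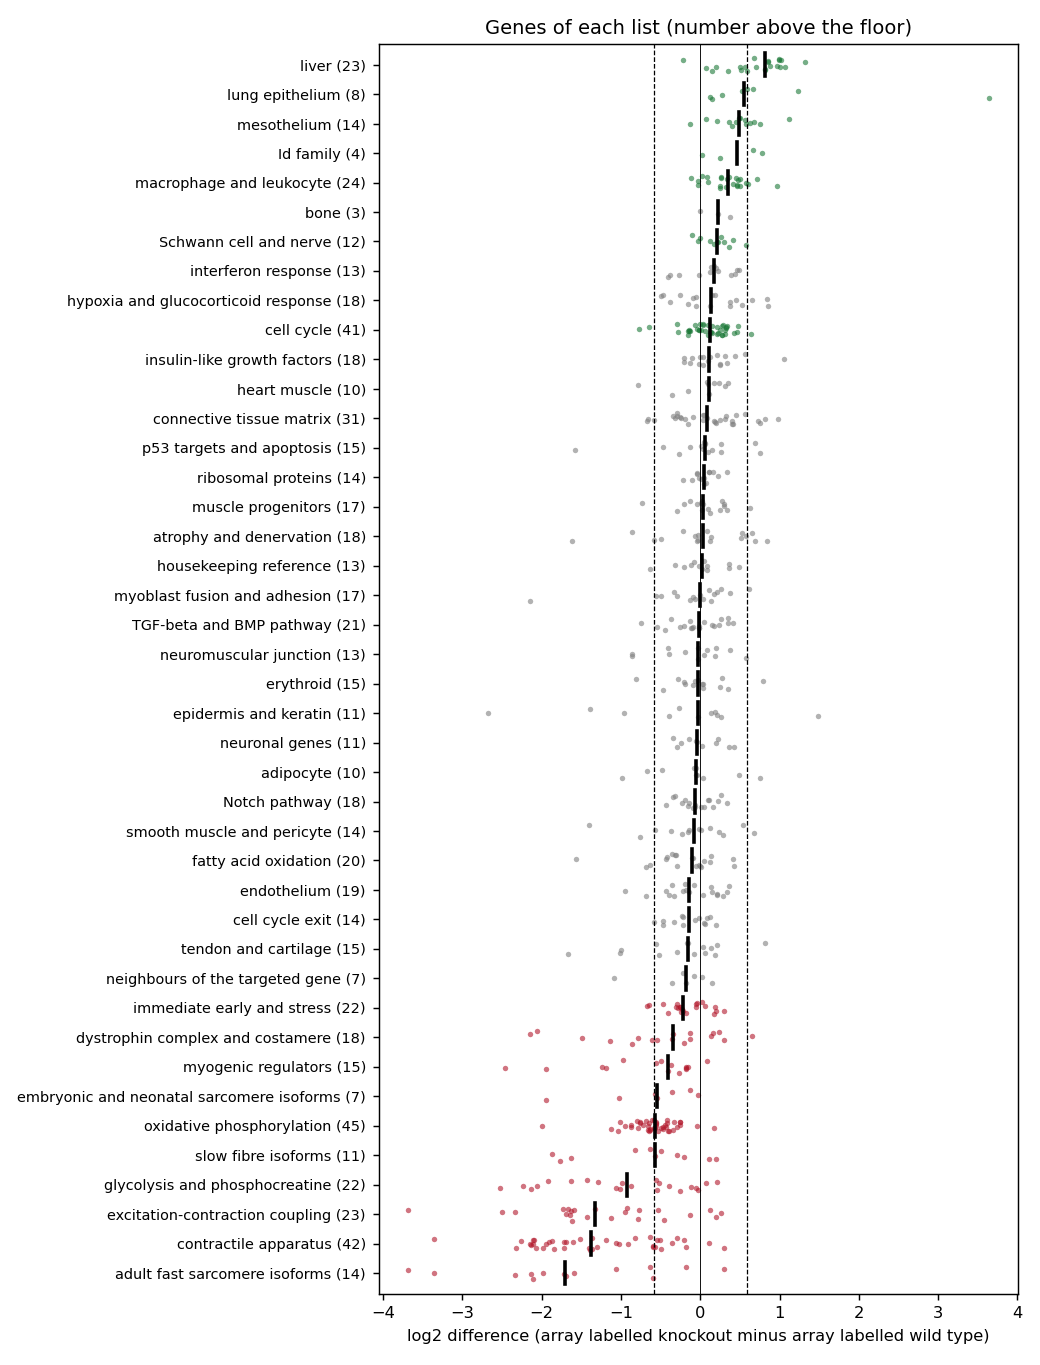
Each point is a gene of a list fixed in advance, placed by its log2 difference (array labelled knockout minus array labelled wild type), with black bars at list medians, dashed lines at the 1.5-fold size rule, and red and green for lists below or above the central 95% of matched random lists; the sex-linked list is not drawn. The medians run from -1.71 for adult fast isoforms to 0.82 for liver genes.

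Regulators of myogenesis were lower in part. The median of 15 regulators was -0.40, below 9999 of the random lists, with 5 lower by the size rule and 0 higher. Myf6 (MRF4), the myogenic factor of differentiating and mature fibres, was lower by 5.51-fold (-2.46), and Myf5, a factor of early myoblasts, by 3.84-fold (-1.94), although its signal of 5.10 on the array labelled knockout lay under the floor. Smarcd3 (-1.24), Eya4 (-1.19) and Mef2c (-0.97) were the other 3, and all 5 probe sets of Mef2c were lower. Myogenin (Myog, 0.09) and MyoD (Myod1, -0.18), the factors that drive muscle differentiation, differed by less than the probe set SD. Mef2d (-0.56), Vgll2 (-0.49), Mef2a (-0.40), Eya2 (-0.37), Tead4 (-0.27), Srf (-0.18) and Tead1 (-0.16) were within the size rule. Six4 was at -0.19 on its brightest probe set, but at -1.61 and -1.60 on 2 others, whose signals of 4.64 and 4.76 on the array labelled knockout lay under the floor.

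Id genes, which encode inhibitors of MyoD-type factors and which RP58 is known to repress in muscle, were higher or near 0. Id3 was higher by 1.71-fold (0.78) and Id1 by 1.59-fold (0.67). Id2 differed by 0.25 on its brightest probe set and by 0.63 on another, and Id4 by 0.02. The median of the 4 genes was 0.46, above 9911 of the matched random lists. Markers of liver (0.82), lung (0.56), mesothelium (0.49) and leukocytes (0.35) were higher on the same array. Without probe sets of the _s_at, _x_at and _a_at kinds, only 2 of the 4 genes could be read, and their median lay above 94.2% of random lists.

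**Figure D3:**
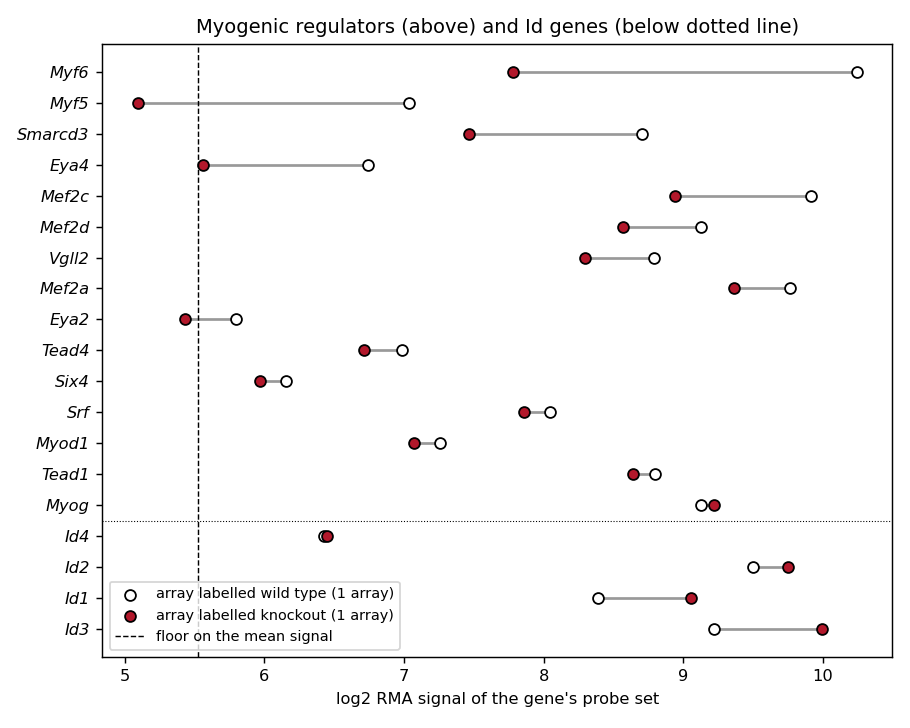
For each myogenic regulator and Id gene, the log2 RMA signal is shown on the array labelled wild type (open circle) and on the array labelled knockout (red circle), 1 array each, with a dashed line at the floor. Myf6 and Myf5 show the widest gaps, Myog and Myod1 nearly coincide, and Id1 and Id3 lie to the right on the array labelled knockout.

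Markers of muscle progenitors did not stand apart as a list, with a median of 0.04 over 17 genes. The homeobox gene Meox2 was lower (-0.74), the syndecan gene Sdc4 higher (0.63), and Vcam1 was at 0.33, while Pax7 and Pax3, transcription factors of muscle stem and progenitor cells, differed by 0.31 and 0.10. Notch pathway genes had a median of -0.07, and 0 of 18 passed the size rule. The largest differences were those of Dll4 (-0.43), Notch1 (-0.34) and Dlk1 (0.33), and Dlk1 was at -0.21 when its 2 probe sets were averaged. TGF-beta and BMP pathway genes had a median of -0.02, with Tgfb2 at -0.75, Bmp2 at -0.54 and Tgfbr1 at -0.44. Insulin-like growth factor genes had a median of 0.11, with Nckap1 (0.32), to which the symbol H19 had led, counted among them. Igfbp2, an IGF-binding protein gene, was higher by 2.08-fold, with Igfbp5 at 0.57 and Igfbp6 at 0.44.

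Genes of glycolysis and oxidative phosphorylation were lower. Of 22 genes of glycolysis and the phosphocreatine shuttle, 12 were lower and 0 higher, with a median of -0.92. The 22 include Pigq (-0.03), to which the symbol Gpi1 had led. The mitochondrial creatine kinase gene Ckmt2 (5.73-fold lower), Ampd1 (4.72-fold) and the muscle phosphoglycerate mutase gene Pgam2 (4.39-fold) led the list. Of 45 oxidative phosphorylation genes, 44 were below 0 and 21 passed the size rule, with a median of -0.56 (95% interval over genes -0.64 to -0.47). The muscle isoforms Cox7a1 (3.99-fold lower) and Cox6a2 (-1.13) were among its members, with Ndufa5 at -1.04. The markers of liver, mesothelium and lung were higher on the same array. Both lists lay below all matched random lists. Genes of fatty acid oxidation did not stand apart, with a median of -0.10 and 3 of 20 lower: the fatty acid carrier Fabp3 (-1.57), the transporter Cd36 (-0.68) and the coactivator Ppargc1a (-0.63).

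Cell cycle genes were slightly higher as a list. Their median of 0.13 over 41 genes lay above 9963 of the random lists, yet only Hmmr (0.64) was higher by the size rule and Ccne2 (-0.77) and Melk (-0.64) were lower. The 4 probe sets of Hmmr ran from -0.11 to 0.64. Cdc20 and Plk1, both mitotic genes, were at 0.48 and 0.46. The list differed in the same direction as the markers of liver (0.82), mesothelium (0.49) and leukocytes (0.35). Genes of cell cycle exit had a median of -0.14, with Rb1 at -0.58, and Gadd45g and Cdkn1a (p21) both at -0.47. Among p53 targets and apoptosis genes, with a median of 0.06, Ccng1 was lower by 3-fold, and Bcl2l11 (0.76) and Fas (0.69) were higher. In the atrophy and denervation list, with a median of 0.03, the ubiquitin ligase gene Trim63 (MuRF1) was lower by 3.06-fold and Chrna1 also lower, and the metallothionein genes Mt1 (1.79-fold) and Mt2 (0.66) and the autophagy gene Gabarapl1 (0.69) were higher.

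Markers of tissues next to the diaphragm were higher on the array labelled knockout. Of the liver genes, 15 of 23 passed the size rule and 0 were lower, with a median of 0.82 (1.76-fold) above all matched random lists. The 23 include Trh (0.15), to which the symbol Trf had led. Hpx (1.32), Apoc1 (1.07) and Fgb (1.01) led the list. Albumin (Alb) was at 14.23 and 14.30, the top of the scale, on the arrays labelled wild type and knockout, so liver transcripts were abundant on both. Mesothelium genes had a median of 0.49, with 4 of 14 higher, namely Krt19 (1.12), Krt7 (0.75), Upk3b (0.68) and Msln (0.62). Lung epithelium genes had a median of 0.56, with 4 of 8 higher, namely Sftpc (3.64), Ager (1.24), Foxa2 (0.67) and Aqp5 (0.59). The median of macrophage and leukocyte genes was 0.35, led by the granule genes Camp (0.97) and Ngp (0.71), with Lyz2 at 0.60. All 3 lists lay above every matched random list. The Schwann cell and nerve list had a median of 0.22, above 9897 of the random lists, with 0 of 12 genes past the size rule and Erbb3 (0.58), Mbp (0.42) and Stmn2 (0.36) in front. Another probe set of Erbb3 was at -0.19. The list lost this place under some alternatives, including the one with no floor (0.12).

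Other cell types did not stand apart in the main setting. Without _s_at, _x_at and _a_at probe sets, tendon and cartilage (-0.31) and smooth muscle and pericyte genes (0.24) did. Connective tissue matrix genes had a median of 0.08, with elastin (Eln, 0.99), Fmod (0.81), Fbln2 (0.75) and Sparc (0.72) higher and Tcf4 (-0.67), Thbs2 (-0.66) and Mfap4 (-0.59) lower. Tendon and cartilage genes had a median of -0.15, with the tendon genes Tnmd (-1.67) and Thbs4 (-1.02), and Cilp (2.01-fold), lower and Fmod higher. Endothelial genes had a median of -0.14, with Aplnr (-0.95) and Cldn5 (-0.69) lower and Pecam1 at -0.44. Erythroid genes had a median of -0.03, with the embryonic globin gene Hba-x lower (-0.80), Car1 higher (0.79) and Hbb-y at -0.46. The medians were -0.08 for smooth muscle and pericyte genes (Des -1.40, Smtn -0.76, Myh11 0.67), -0.06 for adipocyte genes (Slc2a4 -0.98, Cebpa 0.76, Cidea -0.67), 0.11 for heart genes (Gata4 0.35, Nppb 0.31, Tbx5 0.24, Sln -0.78) and -0.04 for neuronal genes (Dcx 0.42, Elavl3 -0.35). The epidermis and keratin list had a median of -0.03 with members far apart: Flg was at -2.67, with a signal of 4.19 on the array labelled knockout under the floor, Krt10 at -1.40, Krt1 at -0.96 and Krt14 at 1.49. Only 3 of 12 bone genes were above the floor, with a median of 0.22, Ifitm5 at 0.38, Alpl at 0.22 and Sp7 at 0.00.

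Immediate early and stress genes were lower as a list. Their median was -0.22, below 9933 of the random lists, with 2 of 22 genes past the size rule, Ccn2 (-0.67) and Atf3 (-0.65), and Hspa1b at -0.47. Hypoxia and glucocorticoid response genes had a median of 0.14, with Angptl4 (0.85), Mt1 (0.84) and Mt2 (0.66) higher. Interferon response genes had a median of 0.17, with B2m at 0.49, Gbp2 at 0.46 and Usp18 at 0.44. Both lay inside the central 95% of random lists, as did the ribosomal proteins (median 0.05, with Rpl8 at 0.34, Rpl4 at 0.22 and Rps14 at -0.22) and the housekeeping reference genes (median 0.02, with Sdha at -0.63, B2m at 0.49 and Actb at 0.36). Genes that neighbour Zbtb18 had a median of -0.18, with Efcab2 lower by 2.13-fold, to a signal of 5.18 under the floor, Sdccag8 at -0.36 and Cep170 at -0.22. In all, 10 of the 43 lists lay below the central 95% of random lists and 7 above it.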

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

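These results come from probe sets that no comparison used, because the annotation at hand gave them no gene symbol or several. The largest difference on the arrays was that of an unnamed probe set, which was higher on the array labelled knockout by 6.51 on the log2 scale, from 3.07 to 9.58. Another 2 unnamed probe sets were higher by 4.40 and 3.87, from 3.70 and 3.62. The lower signal of all 3 lay under the floor, so the sizes are uncertain. The Y-linked genes Eif2s3y (3.59 to 8.58) and Kdm5d (4.09 to 7.40) had a like pattern, and 1 gene of the sex-linked list had no named probe set. Which genes the 3 probe sets read is not given in the annotation at hand. Whether they belong to the sex-linked difference was not tested. Of 3310 unnamed probe sets above the floor, 106 were higher and 61 lower by the size rule, and the lowest was at -2.91. Of 632 probe sets with several gene symbols, 27 were higher and 43 lower.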

How the results depend on the processing

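The sign of the median held for the 17 lists outside the central 95% of random lists, and the sign of the difference for the named genes past the size rule, under the alternatives of probe set, floor and centring fixed in advance. Of 117 medians of these lists under those alternatives and without shared members, 112 stayed outside the central 95% and within the interval over genes, and 830 of 858 values of named genes moved by less than the probe set SD. A change of floor cannot alter a gene's brightest probe set, and median centring shifted every value only by the median difference of -0.003. The share for named genes was therefore largely fixed in advance. That for list medians was so in part, although a change of floor can alter which genes a list holds. The counts depended on the size rule: 326 genes were lower and 128 higher at 2-fold, and 521 and 251 beyond the 95th percentile of probe set disagreement. Scaling to the poly-A spike-ins, added after the data were seen, moved the median of all genes to 0.74, gave 9990 genes higher and 182 lower, and turned the sign of 6 of the 17 lists, while differences relative to the median gene stayed as they were. A rise of every difference could turn only the 10 lower lists. Those turned were oxidative phosphorylation, slow fibre isoforms, embryonic and neonatal isoforms, myogenic regulators, the dystrophin complex, and immediate early and stress genes. Without _s_at, _x_at and _a_at probe sets, the Id list (median 0.40, 2 genes) and the Schwann cell list (0.22) no longer stood apart, oxidative phosphorylation was at -0.70, tendon and cartilage (-0.31) and smooth muscle (0.24) stood apart, and the sex-linked list was at 1.05. The Schwann cell list also lost its place with no floor (0.12) and without members of other lists (0.19). The mean over probe sets put the interferon list (0.17) and the sex-linked list (0.52) outside the central 95%. The sex-linked list was outside it too with no floor (-0.27) and at the higher floor (-0.92, 3 genes). The cause was not tested for these changes. Random lists not matched on signal changed 0 calls. No replicate could be left out with 1 array per group. No paired analysis was possible because each group holds 1 array. RMA compresses the differences of dim genes near the floor and of genes near the top of the scale, such as Alb and Acta1.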

Other observations

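The gene families and the tests in this part were chosen after the main comparison was seen, except the second liver and lung lists and the count of neighbours without list members, whose criteria were set before their values were looked at. The pattern for family 2 cytochrome P450 genes was narrowed after a first value was seen, because it also took in families with longer numbers, and had a median of 0.34 before. Of 29 gene families read by their symbols, 10 lay below and 4 above the central 95% of matched random lists. Because the families were picked with the data in view, and Asb5 and Asb12 were already among the 10 lowest genes, these counts have no chance level to be set against. Mitochondrial families beyond the respiratory chain were lower. Mitochondrial ribosomal genes had a median of -0.38 for the small subunit (9 of 29 lower by the size rule, led by Mrps36 at -1.01) and -0.38 for the large subunit (14 of 47 lower), while cytosolic ribosomal genes were at 0.00 and 0.07. Genes of coenzyme Q synthesis had a median of -0.70, with 7 of 11 lower, among them Coq9 (-1.36), Coq10a (-1.34) and Coq7 (-1.13). Mitochondrial import genes had a median of -0.25, with 4 of 21 lower. Mitochondrial carriers had a median of -0.13 and went both ways, with 6 of 38 lower, led by Slc25a12 (4.21-fold), and 2 higher, Slc25a47 (0.97) and Slc25a13 (0.71).

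Ubiquitin ligase adaptors of the Asb family differed in size. The median of 15 genes was -0.22, with Asb5 (-2.76), Asb12 (-2.75), Asb2 (-1.21) and Asb8 (-0.98) among the 6 that passed the size rule, and Asb3, Asb9 and Asb18 within 0.06 of 0. The medians of kelch-like genes (-0.23, with 4 of 27 lower by the size rule), proteasome genes (-0.25, 2 of 37), F-box genes (-0.13, 1 of 28, and 1 higher) and zinc finger genes (-0.08, 10 of 230) also lay below the random lists' central 95%, although the last 3 had a smaller share of lower genes than the 6.51% of all genes and the intervals over genes of the kelch-like and F-box families include 0. Potassium channel genes lay inside it (0.06, with 0 of 48 past the size rule). Of the 4 families that were higher, 2 are known mainly for liver proteins: clade A serpins had a median of 0.70, with Serpina6 at 1.71 and Serpina7 at 1.63, and family 2 cytochrome P450 genes had a median of 0.53, with Cyp2f2 at 1.60. The other 2 were olfactory receptors (0.21, with 1 of 16 past the size rule, Olfr64) and fibroblast growth factors (0.23, with Fgf1 higher at 0.67 and Fgf13 lower at -1.78 among 12), and the intervals over genes of both include 0.

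Muscle genes were lower on the array labelled knockout. The contractile median was still -1.33 after centring by loess on signal. The arrays were already quantile normalised, and such centring does not undo compression of the scale, so this cannot decide whether compression plays a part. With the contractile genes grouped by wild-type signal, the median was -1.73 for the dim, -1.16 for the middle and -1.27 for the bright group. The lower values were therefore not confined to a single range of signal. A smaller share of muscle in the sample would lower muscle transcripts by a common factor, whereas 28 contractile genes with wild-type log2 signals of 8 to 13 ran from -3.36 to -0.21 with an SD of 0.79, against 0.28 between probe sets of a gene. That set left out 3 genes also made outside muscle, a choice made after a first SD of 0.81 was seen, and the spread between embryos is unknown, so less muscle and an effect of genotype cannot be told apart. The samples read as different in sex, with Xist at -4.51. Whether sex plays a part in the lower muscle genes stays open too, because each label has 1 array.

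The higher liver genes may reflect more liver tissue in the sample labelled knockout, although the muscle was dissected under a microscope. A second list of 50 hepatocyte genes, none of them in the first list or the top 10, had a median of 0.88. Of its genes above the floor, 43 of 43 were above 0 and 33 passed the size rule. It lay above all 10000 random lists. Genes of a single cell type tend to differ together, so a high second list was likely once the first was high. The second list therefore cannot tell the source of the difference. Alb (0.07) and Afp (0.20) differed little, at signals near 14, the top of the scale. Dimmer probe sets of Afp, with wild-type signals of 5.86 and 6.92, were at 0.41 and 0.16. Apoa1 differed by 0.68 with a signal of 14.07 on the array labelled knockout. Whether the scale accounts for the small differences of Alb and Afp therefore stays open. For lung tissue the evidence was mixed. A second lung list lay above 9848 of the random lists, but its median of 0.15 was under the size set in advance. In that list 14 of 22 genes were above 0. Of the other surfactant genes, Sftpb differed by 0.12 and Sftpd by 0.53. Sftpa1, whose mean signal lay under the floor, differed by 1.33 on 1 probe set and by 0.26 on another. The source of the Sftpc signal stays open. In the first lung list, all 8 genes above the floor were above 0, with a median of 0.56, and both probe sets of Ager were at 1.24. The genotype and the dissection cannot be told apart for the liver or the lung genes, because only 1 sample carries each label.

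Genes near Zbtb18 differed more often than genes elsewhere. Of 41 genes in a row centred on it, 12 passed the size rule, 8 lower and 4 higher. Of 12466 such stretches on other chromosomes, 22 (0.176%) held as many, with a mean of 4.21 and a highest count of 14. The stretches were taken by moving 1 gene at a time, so neighbouring ones share most of their genes and are not separate loci. The share is therefore no measure of how rare such a count is. The 12 genes near Zbtb18 include Ifi202b (6.66-fold higher, from a signal under the floor), Ifi204 (2.97-fold lower) and Sccpdh (3.41-fold lower on 1 probe set and 0.01 on another), but also Coq8a (2-fold lower), Cox20 (-0.82) and Tfb2m (-0.78), which act in mitochondria, and Apcs (0.88), a liver serum protein gene. Whether the muscle and liver patterns account for part of the excess stays open: none of the 12 is in a list other than that of the neighbours, so leaving out list members, which gave 13 in a wider stretch, tested nothing. A candidate explanation is a stretch of DNA from another strain carried along with the targeted allele, and a direct effect of the lost repressor on its neighbourhood is untested.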
